A study of Mus musculus with 10 samples.

How the data were processed

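Whole extraorbital lacrimal glands (the tear-secreting gland that lies in front of the ear in mice) of 8-week-old female mice were profiled by bulk RNA sequencing, with 4 wild-type and 6 CD25KO libraries. Per the labels' protocols, total RNA was reverse transcribed from an oligo-dT primer with a Lexogen kit and second strands were started from a random primer, so that each read counts a transcript near its 3' end and the count does not scale with transcript length. The submitters' processing notes name cutadapt, FastQC, STAR, HTSeq and DESeq2 and the mouse genome build GRCm38, without versions. The annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here.

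The deposited counts are whole-number read counts per Ensembl gene for 54232 genes in 10 libraries. Per the labels, each column's number is the library number given in 1 sample's description, and every column was assigned to its sample through that number. A second deposited table holds normalized values. Tested on the values, each column equals log2 of the count divided by 1 factor per library, plus 1, and the 10 factors equal DESeq2 size factors computed here from the counts. It served only to recover those factors. Gene symbols were taken from the GENCODE gene names of GRCm38, in which 54079 of the 54232 identifiers matched and 153 did not. Coordinates are 1-based positions in that build.

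Library totals ranged from 9.83 to 32.9 M counts and 13251 to 19347 genes had at least 1 count. Counts were tested with edgeR 4.0.16 (R 4.3.3) using TMM scaling, filterByExpr (minimum count 10, minimum total 15) with the group, a robust quasi-likelihood fit with genotype as the only term, and Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05 over 14913 tested genes. CPM values were computed from the TMM-scaled library size. Fold changes are log2 of CD25KO over wild-type with their standard errors, and group values are means ± SD. For a gene at 0 in every wild-type library, the fold is a lower bound against 3 counts over the wild-type group. With 1 to 3 wild-type counts, the ratio of pooled rates is given with its exact 95% counting interval. These bounds and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

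47 gene lists of cell types, functions and RNA quality were fixed before the data were examined. The 46 lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with prior count 2 and a preset inter-gene correlation of 0.01, and again with the correlation estimated and with fry. A list score is the mean log2 CPM of its tested members in a library. Scores were compared by a two-sided exact permutation test over all 210 regroupings, of which the smallest possible p is 0.0048. Over the 6 CD25KO libraries, the T cell score was related to the acinar score by Pearson's r and Spearman's rho with exact permutation p-values.

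Genes named in the text follow a rule fixed before the data were examined. It takes Il2ra, the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM of at least 3 and groups that do not overlap, leaving out gene models and antigen receptor segments. It adds the 2 most abundant members of each list past the threshold, or the 2 most abundant tested members where none passed, and 15 fixed genes of the immune system, of secretion and of sex. Some genes that the rule names are not reported here. Other names were chosen after their values were seen and are said to be so, or are the members behind a list's count.

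Before use, the model was tested on simulated counts with the real means, dispersions and library sizes over 14913 genes. For the comparison of CD25KO with wild-type, it called 1.49% of 67 genes changed 2-fold, 31.3% of 67 changed 4-fold and 62.1% of 66 changed 8-fold with the right sign. Of its 69 calls, 5.80% were on unchanged genes, and it called 0 genes and 0 lists when nothing was changed. In the simulation, 2-fold and 4-fold changes were thus mostly not called. It gave 69 calls against 2521 in the real comparison, so its Benjamini-Hochberg cutoff was stricter. These detection rates therefore do not carry over to the real data. The simulated genes varied independently, and the groups did not differ in composition as the real ones do. The simulation thus does not check list calls with a preset correlation, or calls that rest on the scaling.

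Alternatives fixed before the data were examined were RLE, upper-quartile and the authors' own scaling, library totals alone, DESeq2 1.42.0, limma-voom, 2 other filters on low counts, removal of the 50 most abundant genes, thinning to the smallest total, the library number series as a term, removal of the 2 libraries numbered apart from the rest, and removal of each library in turn. Removal of the libraries that hold parotid gland transcripts was added after seeing the data. No replicate pair in a group agreed within sampling noise, the lowest chi-square per degree of freedom being 126.7, so no library was counted as a repeat of another. No paired analysis was possible because the labels give no numbers shared between wild-type and CD25KO samples. They do not say which mice shared a litter, so litter is not in the model.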

Results

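Lacrimal glands of CD25KO mice were compared with those of mice the series describes as wild-type littermates, all female and 8 weeks old. CD25 is the alpha chain of the interleukin-2 receptor, encoded by Il2ra, and the series was made with Sjögren's disease in view, an autoimmune disease of exocrine glands. The comparison asks how gland transcripts differ between the genotypes. There were 4 wild-type libraries with 9.83 to 32.9 M counts and 6 CD25KO libraries with 13.98 to 27.3 M counts. Each library came from a separately numbered mouse.

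Il2ra (ENSMUSG00000026770, chromosome 2, positions 11642807 to 11693193, plus strand, GRCm38) had few counts in every library. The wild-type libraries 1 to 4 held 0, 5, 0 and 2 counts, and the CD25KO libraries 1 to 6 held 5, 78, 1, 69, 107 and 20. Its level was 0.249 ± 0.366 CPM (SD, n = 4) in wild-type and 1.63 ± 1.57 CPM (SD, n = 6) in CD25KO. The log2 fold change of 2.75 ± 1.53 (SE) did not pass the threshold (edgeR adjusted p = 0.23), and an exact two-sided permutation test on log2 CPM gave p = 0.15. The reads lie near the 3' end and the labels do not say which part of the gene was removed, so these counts do not check the genotype labels. Xist was present in all 10 libraries, with 854 to 12330 counts, and counts of 4 Y-linked genes were 0 except for 2 counts in CD25KO replicate 3.

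The library labelled CD25KO replicate 1 did not hold the main transcripts of the other glands. Bpifa2, a secreted protein abundant in the parotid salivary gland, made up 18.1% of its counts, and 4 of 4 tested parotid markers were higher there than in every other library. Obp1a, an odorant-binding protein gene, made up 6.79% to 15.4% of counts in the other 5 CD25KO libraries and 10.3% to 13.03% in wild-type, but 0.00129% (353 counts) in this library. Wild-type replicate 1 held 3.61% Bpifa2 beside 11.6% Obp1a, and wild-type replicate 4 held 0.272% Bpifa2, whereas the remaining 7 libraries held at most 0.00288%. All libraries were kept in the tests, as fixed before the data were examined.

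**Figure D1:**
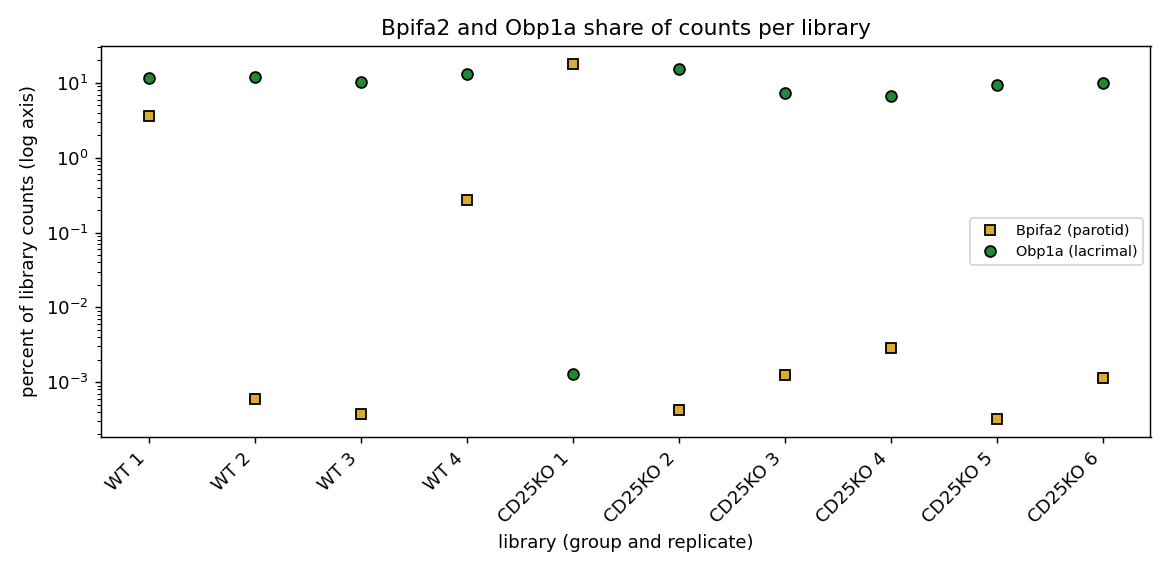
Percent of each library's counts taken by Bpifa2 (squares) and Obp1a (circles) on a log axis, 1 point per library, 4 wild-type (WT) and 6 CD25KO. Obp1a is above 6% in 9 libraries and at 0.00129% in the library labelled CD25KO replicate 1, where Bpifa2 is at 18.1%.

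Of 14913 tested genes, 2521 differed between the genotypes. Transcripts of T cells, B cells, antigen presentation and the interferon-gamma response were higher in CD25KO, and those of endoplasmic reticulum folding and of some secreted proteins were lower with TMM scaling. The counts were 1470 genes higher and 1051 lower, with 2460 changed at least 2-fold (edgeR, adjusted p under 0.05). The groups did not overlap for 2369 tested genes, or 15.9%, where chance gives 0.952%. The first principal component held 41.6% of the variance and separated the genotypes, the library labelled CD25KO replicate 1 lying with the other CD25KO libraries on it. On the third, with 9.90% of the variance, that library was at 89.6 and wild-type replicate 1 at 67.3. The other CD25KO libraries lay between -81.2 and 16.6 there. Without the library labelled CD25KO replicate 1 the counts were 1516 higher and 1201 lower, and without it and wild-type replicate 1 they were 1272 and 1031.

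These counts rest on scaling for composition. The 10 most abundant genes took 60.8% to 70.2% of the counts in wild-type and 20.2% to 49.9% in CD25KO. With library totals alone, 9535 genes were higher and 104 lower, or 98.9% higher against 58.3% with TMM, and the median log2 fold change of all tested genes moved from 0.14 to 1.89. Changes below are relative to the TMM scaling, and the medians given with each list are median log2 fold changes of its tested members. Leaving out wild-type replicate 4 left 927 genes higher and 579 lower, and leaving out wild-type replicate 2 left 657 lower. The library numbers fall in 2 series, 1 of them holding only wild-type replicate 4 and CD25KO replicate 6. Within the other series 655 genes were higher and 428 lower, and with the series as a term 1314 and 936.

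T cell transcripts were few in wild-type glands and higher in all 6 CD25KO libraries. All 16 tested T cell markers rose, over all genes and adjusted over the list alone, with a median log2 fold change of 5.74, or 5.42 with genes at 0 in wild-type set to their bound. Trbc2, a T cell receptor constant region (ENSMUSG00000076498, chromosome 6, 41546730 to 41548352), rose from 3.16 ± 2.26 to 110 ± 57.4 CPM, a log2 fold change of 5.09 ± 0.64 (SE, edgeR adjusted p = 0.000165). Cd8a, the co-receptor of cytotoxic T cells, rose from 0.298 ± 0.525 to 21.8 ± 8.19 CPM, and Cd4 rose from 0.159 ± 0.220 to 6.47 ± 3.22 CPM. Thy1 rose by 2.47 ± 0.47 on the log2 scale. Of 12 CD8 and cytotoxic lymphocyte genes 10 rose, 11 adjusted over the list alone, among them Ccl5 with a log2 fold change of 4.74 ± 0.70, Ctsw with 2.96 ± 0.55 and the pore-forming Prf1, at least 91.8-fold higher. The T cell list (camera adjusted p = 4.7e-14, and adjusted p = 0.044 with an estimated correlation) and the cytotoxic list (median 6.25 or 5.28 at the bound, camera adjusted p = 1.2e-10, and adjusted p = 0.027 with an estimated correlation) were both called. Their scores were higher in 6 of 6 CD25KO libraries than in any wild-type library (exact permutation p = 0.0048, the smallest possible).

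Th1 genes rose together. Of 8 tested members 7 rose, 8 adjusted over the list alone, including Il18r1 with a log2 fold change of 2.62 ± 0.68 (median 4.62 or 3.95 at the bound, camera adjusted p = 1.2e-06, and adjusted p = 0.027 with an estimated correlation). Ifng, the gene of interferon-gamma, was at 0 in wild-type and at 1.61 ± 1.88 CPM (n = 6) in CD25KO, at least 19.4-fold higher (edgeR adjusted p = 0.035). That call was lost without wild-type replicate 1, 2, 3 or 4 or CD25KO replicate 5 or 6, with edgeR adjusted p of 0.052 to 0.085. NK cell markers had 3 of 10 members higher, 6 adjusted over the list alone, or 5 over all genes without wild-type replicate 4, with Klrk1 rising by 3.28 ± 0.81 on the log2 scale (median 3.08, camera adjusted p = 3.0e-05, and adjusted p = 0.027 with an estimated correlation). T cell activation and checkpoint genes had 8 of 10 members higher by both counts, or 5 over all genes without wild-type replicate 4, among them Cd44 with a log2 fold change of 3.65 ± 0.84 and Tox with 4.62 ± 0.66 (median 3.97, camera adjusted p = 8.9e-07, and adjusted p = 0.027 with an estimated correlation). IL-2 family genes and STAT5 targets apart from Il2ra had 9 of 17 members higher, with 12 higher and 1 lower adjusted over the list alone, and 1 lower over all genes without CD25KO replicate 1, such as Il4ra at 1.90 ± 0.52 and Socs2 at 1.72 ± 0.36 (median 2.05, camera adjusted p = 0.00013, and adjusted p = 0.027 with an estimated correlation). Il2 itself was at 4.35 ± 3.67 CPM in wild-type and 4.67 ± 2.88 CPM in CD25KO and did not pass (edgeR adjusted p = 0.94).

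Follicular helper genes had 6 of 8 members higher by both counts, for example Cd200 at 2.11 ± 0.59 and Tox2 at 2.45 ± 0.52 on the log2 scale, with a median of 4.78, or 3.17 at the bound, a camera adjusted p of 6.0e-06 and adjusted p = 0.054 with an estimated correlation. The median was 2.37 to 2.60 over 7 tested members without CD25KO replicate 1, 3, 4 or 5. Foxp3, the transcription factor of regulatory T cells (ENSMUSG00000039521, chromosome X, 7573644 to 7595245), was at 0 in wild-type and 0.794 ± 0.656 CPM (n = 6) in CD25KO, at least 9.58-fold higher (edgeR adjusted p = 0.043), and no longer passed without any 1 of the 4 wild-type libraries (edgeR adjusted p of 0.083 to 0.11). Tnfrsf18 rose from 0.258 ± 0.235 to 13.9 ± 7.12 CPM, and these were the only 2 of 9 regulatory T cell genes past the threshold, against 5 adjusted over the list alone (median 2.88 or 2.29 at the bound, camera adjusted p = 0.0021, and adjusted p = 0.12 with an estimated correlation). Without wild-type replicate 1, 2, 3 or 4 or CD25KO replicate 2, 4, 5 or 6, 1 regulatory T cell gene passed, and the median was 1.52 to 1.77 without those of CD25KO. Ctla4 and Il17a were too low to test, with 21 and 3 counts in all libraries. Th17 genes had 2 of 5 members higher by both counts, Ahr at 1.67 ± 0.50 on the log2 scale and Ccr6 at least 246-fold higher, and the list was not called by camera (median 0.87, camera adjusted p = 0.24). Its score was above all wild-type scores in 6 of 6 CD25KO libraries (exact permutation p = 0.0048). The highest log2 fold change in the list was 11.9, and how far 1 member shapes this score was not tested. The Th17 list had 1 member higher without wild-type replicate 1 or 4 or CD25KO replicate 3 or 5. Gata3, the 1 tested Th2 gene, rose by 3.03 ± 0.82.

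B cell transcripts rose. All 13 tested B cell markers rose by both counts, with a median log2 fold change of 9.66, or 7.26 with genes at 0 in wild-type set to their bound. Spib had 3 wild-type counts and a ratio of pooled rates of 524 (95% counting interval 179 to 2543), and Bank1 rose by 6.12 ± 1.09 on the log2 scale. The list had a camera adjusted p of 1.3e-11 and adjusted p = 0.085 with an estimated correlation, and 6 of 6 scores were above all wild-type scores. Of 14 plasma cell and immunoglobulin genes 4 rose and Derl3 fell by 1.33 ± 0.34, against 9 higher and 1 lower adjusted over the list alone (median 3.10, camera adjusted p = 0.00026, and adjusted p = 0.17 with an estimated correlation). Ighm rose from 5.52 ± 7.10 to 189 ± 165 CPM (edgeR adjusted p = 0.024, and 0.089 without wild-type replicate 2 and 0.083 without wild-type replicate 4). The number of plasma cell and immunoglobulin genes that rose was 7 without CD25KO replicate 1, and 1, 9 and 2 without wild-type replicates 2, 3 and 4, with a median of 4.84 without replicate 3. Derl3 had a log2 fold change of 0.42 with library totals alone. Germinal centre genes had 3 of 5 members higher by both counts, with S1pr2 rising by 2.32 ± 0.47 and Gpr174 at least 97.6-fold higher (median 2.32, camera adjusted p = 0.0021, and adjusted p = 0.071 with an estimated correlation). Lymphoid tissue and high endothelial venule genes had 7 of 8 members higher, 8 adjusted over the list alone, among them Cxcl13, the chemokine that draws B cells, at 4.59 ± 0.75 and Ltb at 4.55 ± 0.69 (median 5.08 or 4.94 at the bound, camera adjusted p = 6.7e-07, and adjusted p = 0.087 with an estimated correlation).

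Of the lists, interferon-gamma-induced genes had the smallest camera p. All 20 tested members rose by both counts, with a median log2 fold change of 4.96, or 4.74 at the bound (camera adjusted p = 4.5e-18, and adjusted p = 0.027 with an estimated correlation). Cxcl9, a chemokine induced by interferon-gamma (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), had the largest rise of the genes that met the size rule, from 0.423 ± 0.506 CPM (n = 4) to 97.4 ± 44.6 CPM (n = 6), a log2 fold change of 8.03 ± 0.69 (edgeR adjusted p = 1.0e-05). Irf1 rose by 3.11 ± 0.46 on the log2 scale. The other largest rises were Gbp2 (6.28 ± 0.80), H2-Q7 (6.19 ± 0.97), AW112010 (5.63 ± 0.83), Ms4a4b (5.29 ± 0.64), Iigp1 (5.10 ± 0.54), Igtp (5.07 ± 0.58) and Hcst (5.04 ± 0.78), beside Ighm and Trbc2, all on the log2 scale. Reads of H2-Q7 and other class I genes can be shared with near-identical copies, so single levels are uncertain. Type I interferon-induced genes had 13 of 22 members higher, 21 adjusted over the list alone, with Oasl2 at 3.04 ± 0.43 and Rtp4 at 2.54 ± 0.31 (median 2.56, camera adjusted p = 1.2e-09, and adjusted p = 0.071 with an estimated correlation).

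Antigen presentation genes rose with them. All 10 class II genes rose by both counts, H2-Aa from 306 ± 132 to 1639 ± 738 CPM and H2-Ab1 by 2.97 ± 0.42 on the log2 scale (median 3.02, camera adjusted p = 2.6e-08, and adjusted p = 0.065 with an estimated correlation). Of 18 class I genes 15 rose, 16 adjusted over the list alone, B2m by 3.76 ± 0.61 and H2-K1 by 3.88 ± 0.61 (median 3.09, camera adjusted p = 3.4e-11, and adjusted p = 0.027 with an estimated correlation). Chemokines had 15 of 23 members higher, 18 adjusted over the list alone, including Ccl5 and Cxcl17 at 2.55 ± 0.37 (median 2.75, camera adjusted p = 1.9e-09, and adjusted p = 0.027 with an estimated correlation). Inflammatory cytokines had 5 of 11 members higher, 7 adjusted over the list alone, 3 over all genes without CD25KO replicate 6 and 2 without wild-type replicate 4, with Il33 at 1.48 ± 0.35 and Csf1 at 1.86 ± 0.49 (median 1.86, camera adjusted p = 0.00066, and adjusted p = 0.071 with an estimated correlation). Endothelial and leukocyte adhesion genes had 8 of 9 members higher by both counts, such as Selplg at 2.76 ± 0.47 and Itga4 at 3.42 ± 0.42 (median 4.57, camera adjusted p = 6.7e-07, and adjusted p = 0.065 with an estimated correlation). Complement genes had 8 of 12 members higher, 9 adjusted over the list alone, with C3 at 2.36 ± 0.36 and Serping1 at 2.44 ± 0.40 (median 2.08, camera adjusted p = 6.0e-06, and adjusted p = 0.10 with an estimated correlation).

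**Figure D2:**
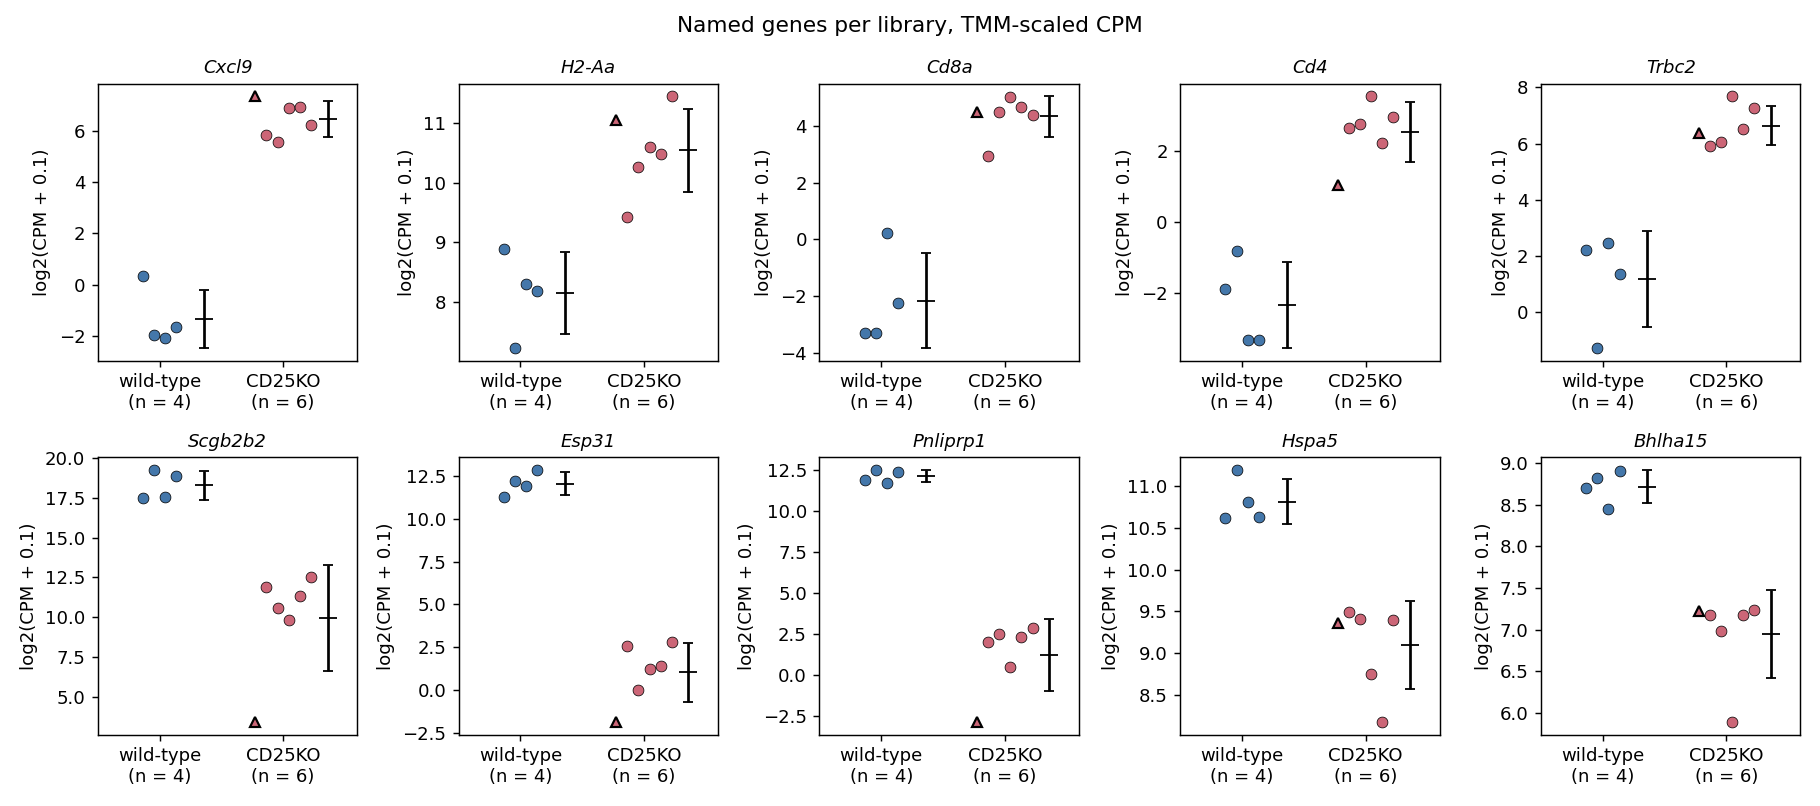
log2(CPM + 0.1) of 10 named genes per library, with the group mean and SD beside the points (wild-type n = 4, CD25KO n = 6) and a triangle for the library labelled CD25KO replicate 1. For each of the 10 genes the groups do not overlap, the upper row being higher and the lower row lower in CD25KO with TMM scaling. With library totals alone Hspa5 has a log2 fold change of 0.06 and Bhlha15 one of -0.0072.

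Macrophage, monocyte and dendritic cell lists were called higher. Macrophage markers had 6 of 13 members higher, 9 adjusted over the list alone, with the lysozyme gene Lyz2 at 2.69 ± 0.39 and C1qb at 1.44 ± 0.43 (median 1.53, camera adjusted p = 0.00048, and adjusted p = 0.12 with an estimated correlation). Monocyte genes had 5 of 7 higher, 6 adjusted over the list alone, with Ccr2 at 3.22 ± 0.62 and Fcgr4 at 3.34 ± 0.59 (median 3.22, camera adjusted p = 0.00085, and adjusted p = 0.071 with an estimated correlation). Dendritic cell markers had 7 of 12 higher by both counts, with Clec10a at 1.73 ± 0.45 and Itgax at 2.58 ± 0.45 (median 2.85, camera adjusted p = 0.00037, and adjusted p = 0.071 with an estimated correlation). Of 6 neutrophil markers S100a8 and S100a9 rose, S100a8 by 6.08 ± 1.06, and S100a9 had 1 wild-type count and a ratio of 353 (95% counting interval 63.2 to 13937), while the list was not called (median 2.94, camera adjusted p = 0.063). It was called without wild-type replicate 1 (median 6.001, camera adjusted p = 0.028), without it and CD25KO replicate 1 (median 5.70, camera adjusted p = 0.031) and without CD25KO replicate 2 or 5 (0.033 and 0.020). Of 6 mast cell markers only Kit, which other cells express as well, rose, by 1.99 ± 0.55, and the list's median was -1.40 with no camera call (camera adjusted p = 0.11). It was called lower without wild-type replicate 4 (0.045), where Kit did not pass. Cathepsins and matrix metalloproteinases had 5 of 17 members higher, 7 adjusted over the list alone, with Ctsb at 1.24 ± 0.36 and Ctsh at 1.37 ± 0.31, and no list call (median 1.24, camera adjusted p = 0.063). It was called without CD25KO replicate 2 or 4 (0.020 and 0.0497). It had 3 members higher without wild-type replicate 2 or 4 or CD25KO replicate 3 or 5. Ctss, the cathepsin of class II processing, rose from 27.1 ± 10.9 to 228 ± 91.7 CPM. Cell death and inflammasome genes had 10 of 19 members higher and Pycard lower, against 12 and 1 adjusted over the list alone (median 2.75, camera adjusted p = 4.2e-06, and adjusted p = 0.065 with an estimated correlation). Zbp1 rose by 3.51 ± 0.51 and Pycard fell by 1.11 ± 0.32, or 0.61 higher with library totals alone. Leaving out 1 library ended some calls, with edgeR adjusted p of 0.050 to 0.10. They were Ahr, C1qb, Cd200, Csf1, Ctsb, Gata3, Kit and Pycard without wild-type replicate 4, Cd200, Clec10a, Ctsb and Il4ra without replicate 2, Ahr, C1qb, Gata3 and Pycard without replicate 1, and C1qb, Ctsb and Pycard without replicate 3. Of the CD25KO libraries, replicate 3 ended Ahr, C1qb, Cd200 and Ctsb, replicate 5 Ahr, Cd200, Ctsb and Pycard, replicate 6 C1qb and Pycard, and replicates 2 and 4 Pycard.

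**Figure D3:**
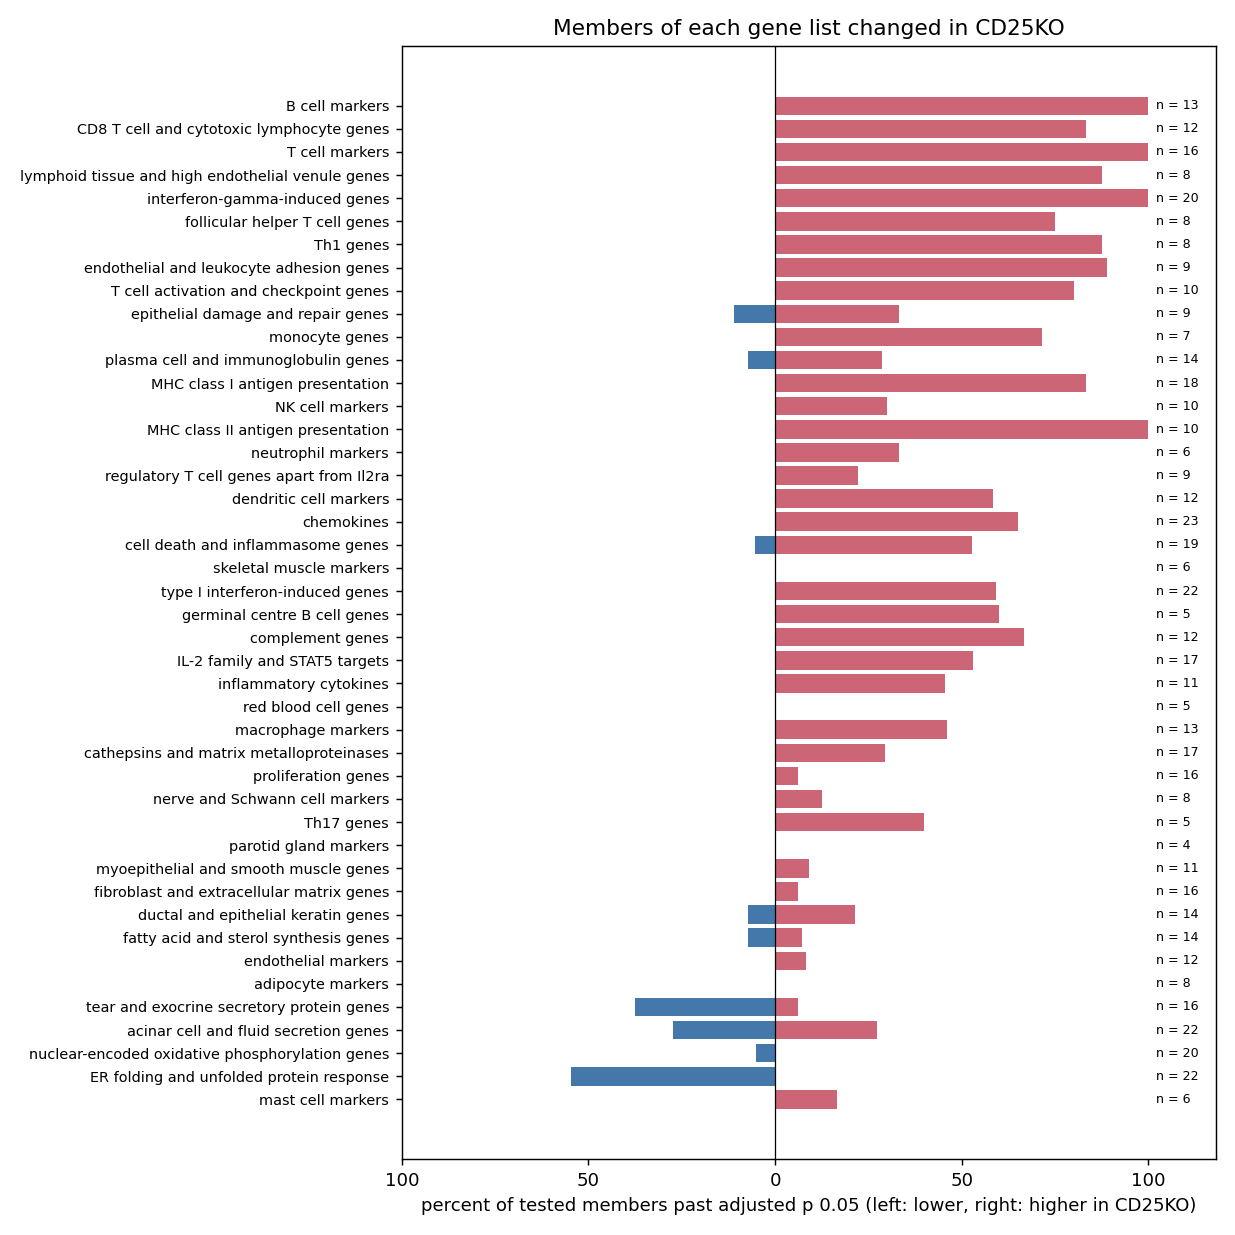
Percent of each list's tested members past the edgeR adjusted p threshold of 0.05 with TMM scaling, higher in CD25KO to the right and lower to the left, for cell type and function lists ordered by median log2 fold change, with the number of tested members. B cell, T cell, class II and interferon-gamma lists reach 100% higher. With library totals alone the endoplasmic reticulum list has 9 members higher and 0 lower.

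The 10 largest falls of the naming rule included 4 secretoglobin and 2 exocrine gland-secreted peptide genes. Scgb2b2 (ENSMUSG00000036521, chromosome 7, 31290508 to 31304977), a secretoglobin of the salivary androgen-binding protein family, fell from 368570 ± 218670 to 2472 ± 2160 CPM, a log2 fold change of -7.22 ± 1.29 (SE, edgeR adjusted p = 0.0015). Scgb2b24 had a log2 fold change of -7.83 ± 1.21, Scgb1b24 of -7.84 ± 1.30 and Scgb2b26 of -7.30 ± 0.78. Esp31, a member of the exocrine gland-secreted peptide family (ENSMUSG00000092342, chromosome 17, 38639447 to 38645653), fell from 4618 ± 2077 to 3.11 ± 2.71 CPM, a log2 fold change of -10.53 ± 0.95 (edgeR adjusted p = 1.3e-05), and Esp15 had one of -7.77 ± 1.10. Pnliprp1, a pancreatic lipase-related gene (ENSMUSG00000042179, chromosome 19, 58728887 to 58744169), fell from 4570 ± 1183 to 3.80 ± 2.69 CPM, a log2 fold change of -10.23 ± 1.00 (edgeR adjusted p = 2.5e-05). The haptoglobin gene Hp (-7.53 ± 0.65), Mucl2 (-7.13 ± 1.47) and Nmrk1 (-7.01 ± 0.98) completed the 10 largest falls. All 10 fell with TMM, RLE, upper-quartile and the authors' scaling and with library totals alone. Secretoglobin and peptide genes belong to families of close copies, so levels of single members are uncertain.

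Of 16 tested tear and exocrine secretory protein genes 6 fell and Lcn2 rose, against 7 lower and 2 higher adjusted over the list alone. The members that fell were Lpo, Esp6, Esp15, Esp16, Esp18 and Scgb2b24. The list's median log2 fold change was 0.24, its mean was -1.22, and it was called lower (camera adjusted p = 0.0050, and adjusted p = 0.12 with an estimated correlation), with 6 of 6 CD25KO scores below all wild-type scores (exact permutation p = 0.0048). Its median turned to -0.21 without CD25KO replicate 2, to -3.27 without the library labelled CD25KO replicate 1 (3 members higher, 7 lower, camera adjusted p = 0.0082) and to -1.54 without it and wild-type replicate 1, and was 1.87 with library totals alone, with 5 members higher and 4 lower. The list includes Dcpp1, named after its values were seen. Dcpp1 had 947138 counts in the library labelled CD25KO replicate 1, 17116 and 1806 in wild-type replicates 1 and 4, and at most 437 elsewhere. The list's score was 10.56 and 9.48 in wild-type replicates 1 and 4, 8.06 and 8.45 in replicates 2 and 3, and at most 7.53 in CD25KO. How far parotid transcripts shape this score was not tested. Lpo, lactoperoxidase (ENSMUSG00000009356, chromosome 11, 87806428 to 87828289), went from 4785 ± 2143 to 1541 ± 736 CPM (edgeR adjusted p = 0.036), a call lost without wild-type replicate 1, 2 or 4 or CD25KO replicate 2, 3, 4 or 5 (edgeR adjusted p of 0.055 to 0.11) and a log2 fold change of 0.07 with library totals alone.

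Genes of protein folding in the endoplasmic reticulum fell together. Of 22 tested members 12 fell and 0 rose, 14 lower adjusted over the list alone, with a median log2 fold change of -1.36 (camera adjusted p = 6.4e-07, and adjusted p = 0.038 with an estimated correlation). Hspa5, the chaperone BiP (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547), went from 1824 ± 364 to 574 ± 174 CPM, a log2 fold change of -1.67 ± 0.39 (edgeR adjusted p = 0.0082), and Dnajc3 had one of -1.63 ± 0.32. All 6 CD25KO scores were below all wild-type scores (exact permutation p = 0.0048). With library totals alone the direction turned, the list's median being 0.37, and Hspa5 had a log2 fold change of 0.06 and Dnajc3 of 0.04.

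Acinar and fluid secretion genes moved both ways. Of 22 members 6 rose and 6 fell, 8 and 7 adjusted over the list alone, with a median log2 fold change of -0.01 and a mean of 0.01, and the list was not called (camera adjusted p = 0.31). Those that fell were Bhlha15, Aqp5, Rab3d, Adra1a, Prlr and Pigr, and those that rose included Slc12a2, Ano1, Itpr2, Kcnn4 and Cftr. Bhlha15, the transcription factor Mist1 of secretory cells (ENSMUSG00000052271, chromosome 5, 144190286 to 144194441), went from 424 ± 57.1 to 129 ± 35.4 CPM, a log2 fold change of -1.72 ± 0.32 (edgeR adjusted p = 0.0022). The water channel Aqp5 (ENSMUSG00000044217, chromosome 15, 99590782 to 99594829) went from 726 ± 522 to 241 ± 111 CPM (edgeR adjusted p = 0.029), a call lost without wild-type replicate 2 or 4 or CD25KO replicate 3, 4 or 5 (edgeR adjusted p of 0.052 to 0.15). Kcnn4 rose from 111 ± 50.1 to 425 ± 205 CPM. Without wild-type replicate 2 or 4, 3 members rose, and leaving out 1 library moved the median between -0.20 and 0.11. With library totals alone Bhlha15 had a log2 fold change of -0.0072, Aqp5 one of 0.19, and the list's median was 1.71.

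Of 7 other epithelial and stromal lists, camera called 1, that of epithelial damage and repair. Ductal and epithelial keratin genes had 3 of 14 members higher and 1 lower by both counts, Wfdc2 at 1.41 ± 0.36 and Sox9 at -1.13 ± 0.37 (median 0.62, camera adjusted p = 0.23). Epithelial damage and repair genes had 3 of 9 higher and Sox9 lower, 6 and 1 adjusted over the list alone, with Lcn2, a secreted iron-siderophore-binding protein, rising from 3.13 ± 0.902 to 37.1 ± 15.7 CPM, and this list was called higher (median 3.30 or 2.90 at the bound, camera adjusted p = 0.0045, and adjusted p = 0.057 with an estimated correlation). Its median was 1.85 without CD25KO replicate 1 and 2.05 without replicate 6, and 5 members rose without wild-type replicate 1. Myoepithelial and smooth muscle genes had 1 of 11 higher and 0 adjusted over the list alone, Krt5 at 1.22 ± 0.39, or 3 higher without CD25KO replicate 1 (median 0.76, camera adjusted p = 0.31). Fibroblast and matrix genes had 1 of 16 higher and 0 adjusted over the list alone, Pdgfra at 1.92 ± 0.59 (median 0.74, camera adjusted p = 0.13), and were called higher, with 2 members, without CD25KO replicate 2 (0.014), and had 2 members higher without wild-type replicate 1 as well. Endothelial markers had 1 of 12, Pecam1 at 1.99 ± 0.52 (median 0.56, camera adjusted p = 0.25), and nerve and Schwann cell markers 1 of 8, Sox10 at 1.96 ± 0.41 (median 0.89, camera adjusted p = 0.27), by both counts. None of 8 adipocyte markers passed by either count, Lpl being at 0.25 ± 0.45 and Cfd at 0.41 ± 0.82, and 1 member rose without wild-type replicate 2 or without the library labelled CD25KO replicate 1, where the median was -0.35 (median 0.49, camera adjusted p = 0.64). The calls of Sox9, Krt5 and Pdgfra were each lost without wild-type replicate 1 or 4 or CD25KO replicate 3 or 5, Krt5 and Pdgfra also without wild-type replicate 3 or CD25KO replicate 2, Sox9 and Krt5 without wild-type replicate 2, Sox9 and Pdgfra without CD25KO replicate 4, and Krt5 without CD25KO replicate 6 (edgeR adjusted p of 0.050 to 0.17). Sox9 was at 0.57 with library totals alone.

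Lists of other tissues and of RNA quality gave these values. Skeletal muscle markers passed in 0 of 6 by either count, Tnni2 being at 2.85 ± 1.80 and Tnnc2 at 2.51 ± 2.79, and their score was 3.69 in wild-type replicate 1, 6.41 and 5.36 in CD25KO replicates 1 and 2, and at most -0.06 elsewhere (median 2.68, camera adjusted p = 0.53). Parotid markers passed in 0 of 4 by either count, with Bpifa2 at 0.82 ± 3.40 and Amy1 at 0.52 ± 3.20, a positive median of 0.86 and a score difference of -2.78 (camera adjusted p = 0.25). Without the library labelled CD25KO replicate 1 both genes were called lower, Bpifa2 at -11.30 (edgeR adjusted p = 0.013) and Amy1 at -10.07 (edgeR adjusted p = 0.018), as wild-type replicates 1 and 4 hold parotid transcripts. Red blood cell genes passed in 0 of 5 by either count, Hba-a1 at 0.88 ± 0.66 and Hbb-bs at 1.84 ± 0.72 (median 1.57, camera adjusted p = 0.48), and were called higher with 2 members without CD25KO replicate 6 (0.024). Proliferation genes were called higher with 1 of 16 members by both counts, Mki67 at 2.24 ± 0.50 (median 0.92, camera adjusted p = 0.023, and adjusted p = 0.48 with an estimated correlation). That call was lost without CD25KO replicate 1 or 6 or wild-type replicate 4 (0.063, 0.085 and 0.14), and 2 and 3 members rose without wild-type replicate 1 and CD25KO replicate 2. Nuclear oxidative phosphorylation genes were called lower with 1 of 20 members by both counts, Uqcrb at -1.98 ± 0.47 (median -0.40, camera adjusted p = 0.0092, and adjusted p = 0.43 with an estimated correlation). Without CD25KO replicate 1, 5 members fell and the median was -0.64, and without wild-type replicate 3 the median was -0.17 and the call was lost (0.079). Mitochondrially encoded genes were called lower with 0 of 7 members by either count, mt-Nd4 at -1.61 ± 0.61 and mt-Nd2 at -1.15 ± 0.56 (median -0.91, camera adjusted p = 0.0050, and adjusted p = 0.19 with an estimated correlation). Without CD25KO replicates 1 and 6 in turn, 2 and 1 members fell, and without wild-type replicate 3 the median was -0.60 and the call was lost (0.069). The medians of both mitochondrial lists were positive with library totals alone, at 1.26 and 0.69, and Uqcrb was at -0.29 and did not pass. Immediate early and heat shock genes had 1 of 12 lower and 0 adjusted over the list alone, Hsph1 at -1.08 ± 0.33 (median 0.85, camera adjusted p = 0.21). The list's score was higher in 6 of 6 CD25KO libraries than in any wild-type library, at 3.63 against 2.66 (exact permutation p = 0.014). Hsph1 was 0.72 with library totals alone and was lost without wild-type replicate 2, 3 or 4 or CD25KO replicate 2, 3 or 6 (edgeR adjusted p of 0.058 to 0.12). Of that list 1 member rose without CD25KO replicate 1 and 2 without wild-type replicate 3. Fatty acid and sterol synthesis genes had 1 higher and 1 lower of 14 by both counts, Elovl5 at 1.64 ± 0.48 and Hmgcs1 at -1.74 ± 0.28, the latter at 0.01 with library totals alone (median 0.58, camera adjusted p = 0.50). Elovl5 was lost without wild-type replicate 2 or 4 or CD25KO replicate 4 (edgeR adjusted p of 0.053 to 0.098), and 2 members of its list rose without wild-type replicate 1. Xist was at 0.69 ± 0.40 and did not pass (edgeR adjusted p = 0.26).

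**Figure D4:**
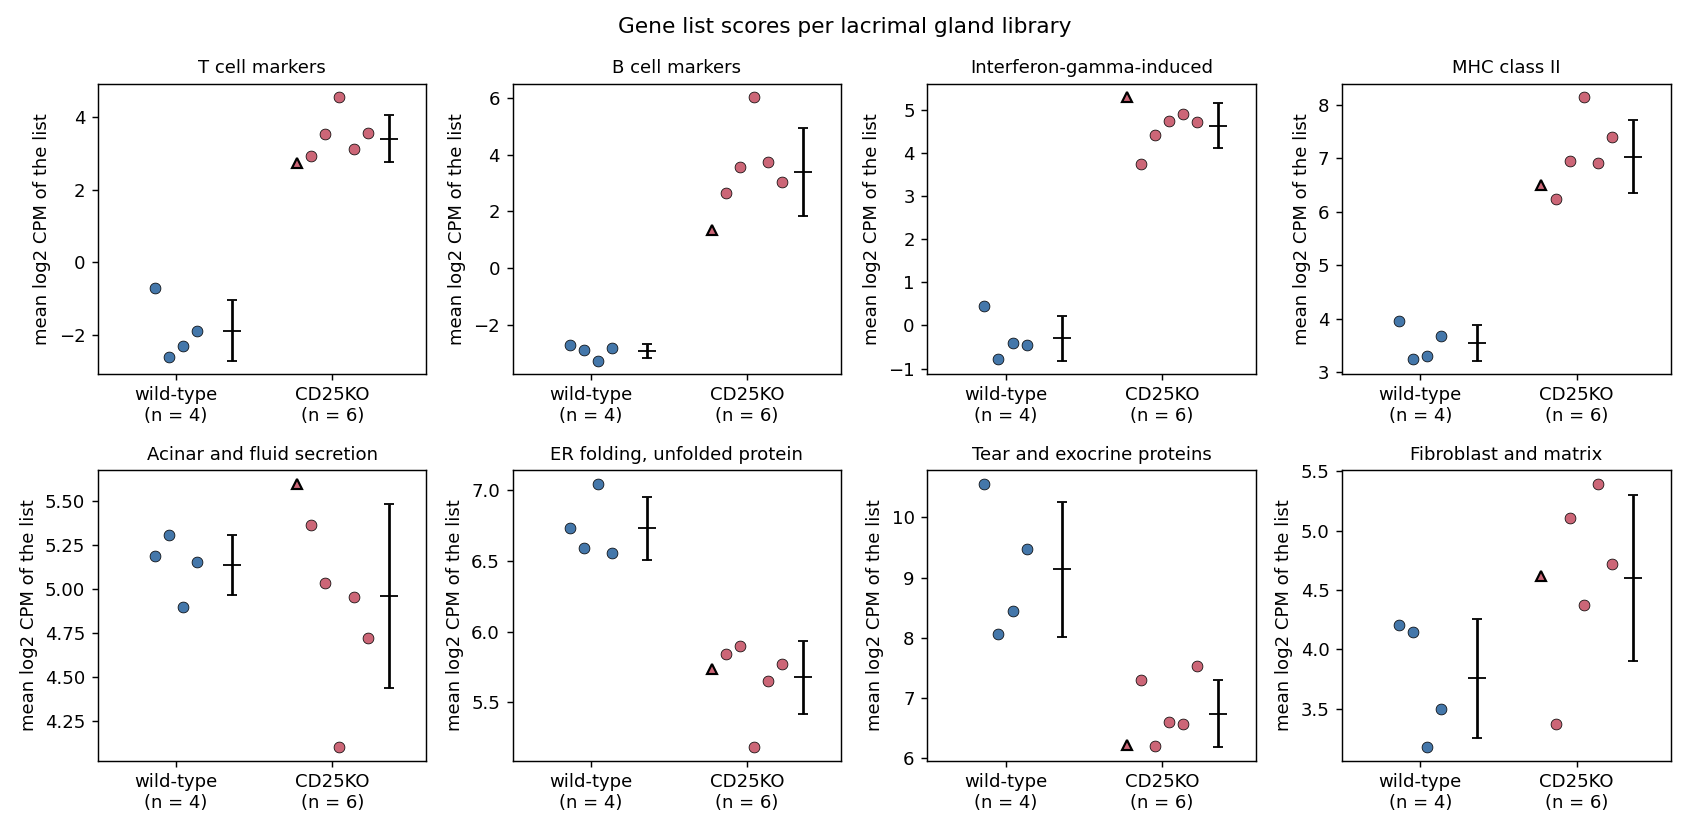
Scores of 8 gene lists, the mean log2 CPM of tested members with TMM scaling, per library with the group mean and SD (wild-type n = 4, CD25KO n = 6) and a triangle for the library labelled CD25KO replicate 1. Groups do not overlap for 6 of the lists and overlap for the acinar and the fibroblast lists. The endoplasmic reticulum list's median turns positive with library totals alone.

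In all, camera called 30 of 46 lists, 26 higher and 4 lower, and 10 held with an estimated correlation, 9 higher and 1 lower. Of the 26 lists called higher, scores lay above all wild-type scores in 6 of 6 CD25KO libraries for all but the plasma cell and the proliferation lists, which had 5 of 6. Of those called lower, 6 of 6 lay below for the tear and endoplasmic reticulum lists, 5 for mitochondrially encoded genes and 1 for oxidative phosphorylation. By the exact permutation test of scores, 35 of 47 lists had a Benjamini-Hochberg adjusted p under 0.05, 32 higher and 3 lower. Among them were 6 lists higher that camera did not call, with adjusted exact permutation p of 0.0080 for Th17, 0.015 for neutrophil, 0.032 for cathepsin and for ductal genes, and 0.021 for immediate early and for fatty acid synthesis genes. Fry called these 6 and the nerve list (0.046) higher, and did not call the proliferation (0.053) and oxidative phosphorylation (0.16) lists. As many lists were called by camera in 10 of 100 splits of the samples, the real one included. These included 3 with 3 wild-type libraries in the group of 4 and 5 with 0. The number of changed genes was reached by the real split alone. Every other split mixes the genotypes within a group, so this cannot exclude chance for the gene counts.

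Within the 6 CD25KO libraries, those with a higher T cell score had a lower acinar score. Pearson's r was -0.96 (exact permutation p = 0.0042) and Spearman's rho -0.94 (exact permutation p = 0.017), the only relation tested. The T cell score ran from 2.75 to 4.57 and the acinar score from 4.099 to 5.5999, with replicate 4 at one end and the library labelled CD25KO replicate 1, which lacked lacrimal transcripts, at the other. Without these 2 samples, the farthest from the median T cell score, r was -0.78 with exact permutation p = 0.21 (n = 4). The relation no longer passed, but the few pairings of 4 libraries leave an exact test little room to pass. It therefore cannot be told whether the relation holds without them. Pearson's r was -0.95 without the library labelled CD25KO replicate 1 (exact permutation p = 0.025) and -0.88 without replicate 4 (exact permutation p = 0.067). Within the larger library number series, without replicate 6, it was -0.96 (exact permutation p = 0.017). The other series holds a single CD25KO library. With library totals alone r was -0.56 (exact permutation p = 0.25).

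**Figure D5:**
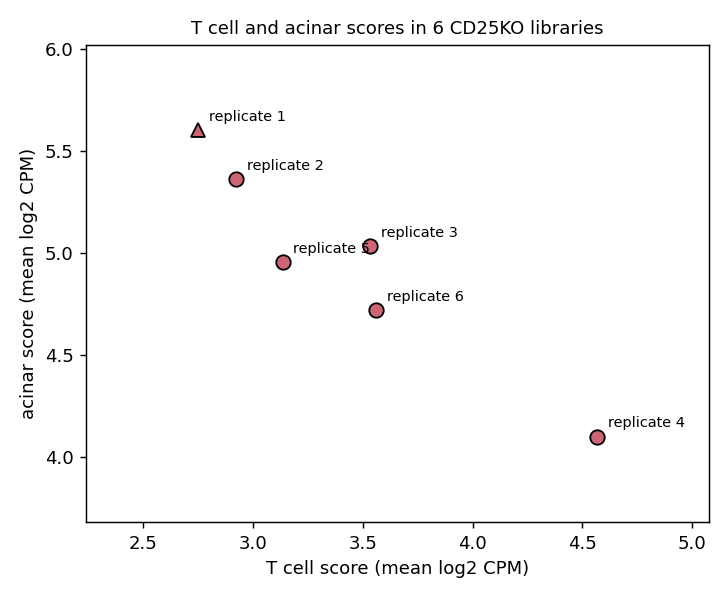
Acinar score against T cell score, both as mean log2 CPM with TMM scaling, for the 6 CD25KO libraries, with a triangle for the library labelled CD25KO replicate 1. Replicates 1 and 4 lie at the ends, and r is -0.96 over all 6 and -0.78 over the other 4.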

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

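The tests of where the parotid transcripts came from were chosen after the transcripts were seen. Each library's value was compared with the rest of its genotype for 161 measures, which gave 322 groups, and 28 of them held a library far from the others by Dixon's test at the 95% level. Chance alone gives about 1 in 20 groups.

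The library labelled CD25KO replicate 1 stood apart in 8 measures. Parotid markers took 20.5% of its counts, against 0.00071% to 0.0035% in the other 5 CD25KO libraries, and their score was 13.25, against -1.04 to 0.46. Its log2 CPM was 17.40 for Bpifa2 (others 0.87 to 3.87), 14.15 for the amylase gene Amy1 (others -0.18 to 1.67), 1.26 for Scgb2b24 (others 6.52 to 9.57) and 3.43 for Scgb2b2 (others 9.83 to 12.54). Its score of plasma cell and immunoglobulin genes was 1.57 (others 4.11 to 5.58) and that of mitochondrially encoded genes 9.64 (others 8.30 to 8.80).

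A mixture of lacrimal and parotid tissue in this library was argued against, because Obp1a, Mup4 and Lcn11, the genes of 3 lacrimal secreted proteins, each had a share of counts at 0.019% or less of that in the lowest other CD25KO library. An effect of the genotype was argued against as well, since the other 5 CD25KO libraries held at most 0.0035% of parotid markers, against 20.5% in this one. Parotid tissue sampled in place of lacrimal gland remains open as a candidate explanation: Obp1a lay 5260-fold below the lowest other library and 4 of 4 tested parotid markers were highest there. The labels hold no record of the dissection. The T cell score of this library was 2.75, against 2.92 to 4.57 in the other CD25KO libraries and at most -0.72 in wild-type, so its immune transcripts may come from a gland other than the labelled one.

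Wild-type replicate 1 held 4.12% of parotid markers (others 0.00053% to 0.31%) and 1.97% of mitochondrial counts (others 1.08% to 1.23%). Its log2 CPM was 5.18 for the skeletal muscle gene Tnnc2 and -1.97 for S100a9, both at the value of 0 counts, -3.53, in the other 3, and 1.72 for Pecam1 (others 2.51 to 2.65). Wild-type replicate 2 had -0.86 for Spib, at 0 counts in the other 3. Wild-type replicate 3 had -2.17 for Ccr2 (others 1.95 to 2.54), 3.96 for Sox10 (others 5.25 to 5.42) and 6.76 for Hmgcs1 (others 6.33 to 6.39). Wild-type replicate 4 had -1.25 for Ltb (others 0.03 to 0.14).

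CD25KO replicate 2 had the lowest scores of type I interferon-induced genes at 3.16 (others 3.81 to 4.13), cell death and inflammasome genes at 2.19 (others 2.83 to 3.18), complement genes at 3.04 (others 4.24 to 4.97) and proliferation genes at 1.15 (others 2.90 to 3.74), and a log2 CPM of 2.96 for Cd8a (others 4.37 to 5.04). CD25KO replicate 4 had the lowest endoplasmic reticulum score at 5.18 (others 5.65 to 5.90), the lowest ductal score at 4.64 (others 5.35 to 5.72) and a log2 CPM of 5.89 for Bhlha15 (others 6.98 to 7.24). CD25KO replicate 6 had 2.82% of mitochondrial counts (others 1.35% to 1.85%) and a log2 CPM of 4.87 for Hbb-bs (others 8.94 to 10.69).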

How the results depend on the processing

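Leaving out the 2 or 3 libraries with parotid transcripts together was chosen after seeing the data, and the other alternatives before the data were examined. With RLE, upper-quartile and the authors' scaling, both other filters, removal of the 50 most abundant genes, thinning and the series term, 2250 to 2678 genes changed and 28 to 32 lists were called, and every count stayed within 1.5 times the reported one.

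Library totals alone gave 9639 changed genes, 9535 higher, 104 lower and 9483 at least 2-fold. 1600 of the 2521 calls were shared and 608 changed sign. The cause lies in its construction, since it leaves out the factor for the few genes that take most wild-type counts. DESeq2 gave 3898 changed and 2470 higher, and limma-voom 1609 changed, 740 higher and 1589 at least 2-fold. The cause was not tested. The 8 libraries of the larger number series gave 1083 changed, 655 higher, 428 lower and 1083 at least 2-fold, and the 7 without parotid transcripts 1401, 836, 565 and 1401, with fewer samples. Leaving out each library in turn gave 1506 (without wild-type replicate 4) to 2717 changed, 927 to 1516 higher, 579 to 1201 lower and 1504 to 2660 at least 2-fold. Without wild-type replicate 2, 657 were lower. Camera with an estimated correlation called 10 lists and fry 35, and DESeq2 gave no list value.

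Il2ra kept its direction and stayed short of the threshold in all alternatives that tested it except library totals alone. There its log2 fold change was 4.55 (edgeR adjusted p = 0.020). Over all alternatives the adjusted p of edgeR, DESeq2 or limma-voom ran from 0.020 to 0.54, the highest with limma-voom. Leaving out 1 library gave log2 fold changes of 2.27 to 4.38. Il2ra had too few counts to be tested with thinned libraries and without CD25KO replicate 2, 4, 5 or 6. The relation of T cell and acinar scores was weaker without the 2 farthest samples (r of -0.78) and with library totals alone (-0.56), and ran from -0.98 to -0.88 when 1 library was left out, the last without CD25KO replicate 4.

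Of 108 named genes besides Il2ra, 96 passed the threshold. Of these, 53 kept direction and call in every alternative that gave a value, 40 lost the call in at least 1, and, overlapping with these, 9 changed direction with library totals alone and 0 in any other alternative. Library totals alone reversed Derl3 (0.42), Pycard (0.61), Aqp5 (0.19), Lpo (0.072), Hspa5 (0.059), Dnajc3 (0.043), Sox9 (0.57), Hsph1 (0.72) and Hmgcs1 (0.0099), and, short of the threshold, mt-Nd4 (0.037) and mt-Nd2 (0.53).

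Other genes short of the threshold changed direction as follows, and of them Bpifa2 and Amy1 passed it as lower without CD25KO replicate 1 (edgeR adjusted p = 0.013 and 0.018) and without it and wild-type replicate 1 (0.027 for both). Bpifa2 and Amy1 were at -4.00 and -3.24 with limma-voom, -0.048 and -0.35 with the series term, -11.30 and -10.07 without CD25KO replicate 1 (up to 3.90 and 3.68 without wild-type replicate 1), -8.23 and -6.92 without it and wild-type replicate 1, and -0.74 and -0.42 without the 3 libraries. Lpl was at -0.084 without CD25KO replicate 1 (up to 0.59 without wild-type replicate 2), -0.02 without wild-type replicate 3, -0.13 without CD25KO replicate 1 and wild-type replicate 1, and -0.075 without the 3 libraries. Cfd was at -0.41 without CD25KO replicate 1 and up to 1.28 without wild-type replicate 1. Il2 was at -0.20 without wild-type replicate 1 or 3, -0.18 and -0.035 without CD25KO replicate 4 or 6, up to 0.66 without wild-type replicate 2, -0.15 without CD25KO replicate 1 and wild-type replicate 1, and -0.0023 without the 3 libraries. Apart from the removal of libraries, the cause was not tested. Depth limits genes near 0 in wild-type, whose effective depth was 5.93 to 14.8 M counts against 22.2 to 41.2 M in CD25KO.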

Other observations

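The tests of the largest falls and of the lymphocyte transcripts below were chosen after these results were seen, and the splits of the samples before. Many, but not all, genes of the exocrine gland-secreted peptide (Esp) and secretoglobin (Scgb1b and Scgb2b) families fell. Of 9 tested Esp genes 8 fell, with a median log2 fold change of -7.77, or 7 with a median of -5.96 with library totals alone. Of 13 Scgb1b and Scgb2b genes, pseudogenes left out, 9 fell, with a median of -5.86, or 9 lower and 1 higher with a median of -4.02 with library totals alone. Scgb1b27 and Scgb2b27, named after their values were seen, had positive log2 fold changes of 3.73 ± 2.04 and 4.39 ± 2.02 and did not pass (edgeR adjusted p = 0.25 and 0.17). Their CD25KO levels were 1033 ± 2286 and 2530 ± 5657 CPM (SD, n = 6). SDs this far above the means of 6 libraries arise only where 1 library holds most of the level. Whether that is the library labelled CD25KO replicate 1, with its parotid transcripts, was not tested. These 2 values therefore do not show a rise shared by the CD25KO glands. Mup5, a major urinary protein gene named after its values were seen, went the other way, with a log2 fold change of 4.85 ± 1.11 (SE, edgeR adjusted p = 0.012). Mup4, named likewise, was at 2.37 ± 1.35 and did not pass (edgeR adjusted p = 0.25). Mup4 had 11 counts in the library labelled CD25KO replicate 1, 164392 to 690882 in the other CD25KO libraries and 9098 to 54093 in wild-type. Mup6 was at -0.36 ± 0.91 and did not pass (edgeR adjusted p = 0.82). Without the library labelled CD25KO replicate 1, 2 of 3 tested Mup genes were higher and 0 lower. These families hold close copies, so shares of single members are uncertain.

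Altogether 66 genes fell by 5 or more on the log2 scale, a group defined after the values were seen, 6 of them Esp and 10 Scgb1b or Scgb2b genes, the pseudogene Scgb1b5-ps included. They held 45.04% to 55.8% of the counts in wild-type, 0.657% to 3.47% in 5 CD25KO libraries and 0.0156% in the library labelled CD25KO replicate 1. The highest median of these genes over the 5 other scalings was -5.26, with library totals alone, where the highest member was at -3.32. The falls thus held under each scaling tried. This could hardly have come out otherwise, because the genes were chosen for their falls with TMM. Library totals moved the median of all tested genes only from 0.14 to 1.89. Parotid tissue was argued against as the cause, as the median of the group was -7.12 without the 3 libraries that held it. Fewer acinar cells as the whole cause would lower the acinar list by about as much, and its median was -0.015, with quartiles of -1.01 and 1.604 and a lowest member of -3.71. The group also holds genes of other functions and gene models. What lowered these transcripts stays open, and no biological explanation beyond the genotype was tested.

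Lymphocyte transcripts near 0 in wild-type could reflect lower effective depth there, but with all libraries thinned to 5.93 M effective counts 15 of 15 tested T cell genes were higher with a median log2 fold change of 5.62. Lymph node tissue carried along with the CD25KO glands cannot be told apart from lymphocytes in the gland. The ratio of B cell to T cell counts spanned 6.77-fold over the 6 libraries, and 3.89-fold without replicate 4, but how far it varies between lymph nodes of different mice is not known from these data. The lowest ratio was in the library labelled CD25KO replicate 1, which held parotid transcripts. Glycam1, a gene of high endothelial venules in lymph nodes, named after its values were seen, had 25, 429, 1086, 8558, 486 and 136 counts in CD25KO replicates 1 to 6 and 0 in every wild-type library. Infiltration of the gland by lymphocytes is the biological explanation the design gives and was not tested apart from this.

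Of 100 splits of the 10 samples into groups of 4 and 6, 1, the real one, gave as many genes changed (2521), higher (1470), lower (1051) or changed at least 2-fold (2460). The highest other split gave 0 for each. Every other split mixes the genotypes within a group, so a genotype difference widens its spread and lowers its calls. The splits therefore cannot exclude chance for these counts. As many lists were called in 10 of 100 splits, the real one included, with 30 lists in the real split and 35 in the highest other, so chance is not excluded for the number of lists called with a preset correlation. Of the 9 other splits with as many lists, 8 had 0 or 3 wild-type libraries in the group of 4 and so still part the genotypes in good measure, while the 48 splits with 2 gave at most 23 lists and the 33 with 1 at most 30. The share of Gm42418, a gene that overlaps ribosomal RNA, ran from 0.0205% of counts in wild-type replicate 4 to 8.85% in CD25KO replicate 4. Its mean was 0.54 ± 0.60% in wild-type (SD, n = 4) and 3.84 ± 3.31% in CD25KO (SD, n = 6). The groups overlapped, with up to 1.40% in wild-type and as little as 0.40% in CD25KO.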
